A study of Homo sapiens with 12 samples.

How the data were processed

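Gene expression was measured on 12 Affymetrix arrays with RNA from cultures of RUES2, a human embryonic stem cell line. Per the labels' protocols, the cells were guided through definitive endoderm and anterior foregut endoderm to lung progenitors, which were sorted by CD47 and then grown in a medium low in Wnt activity. Cells positive and negative for SCGB3A2, a secretoglobin made by airway epithelium, were sorted at day 36. RNA was extracted with QIAzol and RNeasy columns and labelled with biotin by the WT Plus kit, per the labels' protocols.

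The deposited table held 1 log2 value for each of 23786 probe sets on each array, and its values ran from 0.265 to 12.3. Per the submitters' processing notes the authors used RMA with affy 1.36.1 in R 2.15.1, which corrects the background, normalizes the arrays to one another and summarizes probes on the log2 scale. The annotation release behind the probe sets was not given in the sources used here. RMA gives every array nearly the same distribution of values, so a change in the total amount of RNA per cell cannot be seen in them, and differences near the lower end of the scale are compressed. Probe-level signals were not used here, so no call of presence above background was made, and a low value means a signal near the floor of the array, not the absence of a transcript.

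Each probe set was identified by an NCBI gene number. The platform annotation gave exactly 1 gene symbol for 22458 probe sets, several for 0 and none for 1328, and only those with 1 symbol were named. All 23786 probe sets entered the tests, with 0 columns of per-sample values left unused. A gene for which no named probe set was at hand is not reported here.

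Groups and replicate letters came from the labels. The groups were day 0 (n = 2), day 15 CD47hi (n = 2), day 22 (n = 2), day 36 SCGB3A2- (n = 3) and day 36 SCGB3A2+ (n = 3). The per-array medians lay between 3.67 and 3.75, which RMA sets nearly alike. limma's array weights ran from 0.455 for both day 0 arrays to 1.72 for SCGB3A2- B. Depth in the sense of sequencing does not apply to arrays, and their number limits the precision.

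The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group and all 12 arrays in 1 fit, so that the 5 groups shared an estimate of the spread. The fit had 7 residual degrees of freedom and 4.43 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets within a comparison and a threshold of adjusted p under 0.05. Differences are given as log2 values with limma's standard error. A moderated F-test asked for any difference among the 5 groups. Counts of changed probe sets are also given at a log2 difference of 1 or more.

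The lists of genes for lineages, signalling pathways and cell states were written before the data were examined, as were the comparisons, the rule for named genes and the alternatives listed further on. They were 28 lists with 510 entries, of which 483 had a probe set (477 distinct genes), 2 of them through an older symbol. ETV5 stood on 3 lists, and HOPX, AQP5, SLC26A4 and EGR1 each on more than 1. Each list was counted by member and tested with camera at a preset correlation of 0.01 on the same fit, with adjustment over the lists of a comparison. The rule for named genes took the 10 largest increases and the 10 largest decreases of a comparison among characterised genes past the threshold whose arrays did not overlap between the groups, up to 4 members of each list with the smallest adjusted p, and a fixed set reported whatever their values (NKX2-1, SCGB3A2, CD47, POU5F1, FOXA2, SFTPC, SFTPB, SCGB1A1, FOXJ1, AFP, CDX2 and MKI67).

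Replicate letters of the labels were checked for pairing by correlating each array's deviation from its group mean, over all probe sets, with that of the other group. For the sorts of day 36, arrays with the same letter correlated at 0.104 (A), 0.124 (B) and 0.111 (C), and each correlated best with its own letter. Deviations of a sort's arrays from their own mean cancel out, so these day 36 values depend on one another. On this limited basis the letters were taken to pair the day 36 arrays. A fit with the letter as a block, over all arrays, is given beside a result of the day 36 sorts where it changed a call. For day 22 and SCGB3A2- the same correlations were 0.126 (A) and 0.114 (C), similar to those of the day 36 sorts and each best with its own letter. With n = 2 the day 22 deviations mirror each other, so these values are not independent. They were 0.0302 and 0.0584 for day 22 and SCGB3A2+, also best with their own letter, and -0.0112 to 0.059 for the other groups checked. Day 22 and SCGB3A2- may therefore be paired by letter as well, and for the other groups pairing was not established.

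Alternatives were a fit of only the arrays compared, an intensity trend with robust variances, array quality weights, a filter that kept the 16116 probe sets whose highest group mean exceeded 2.96 (the 40th percentile of all values), a repeated quantile normalization, centring on array medians, the replicate block, leaving out each array in turn, camera with an estimated correlation, and fry. Leaving out an array of a group with n = 2 leaves a single array there, which is then assumed to vary like the other groups.

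The fit was tested on simulated data with 200 genes changed among 23786 probe sets. The real comparisons called 1878 to 7499 probe sets. More calls make the Benjamini-Hochberg cutoff looser, so the simulated shares do not carry over directly and may understate recovery in the real data. For the sorts of day 36, the fit recovered 22.4% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 100% of 66 changed 4-fold. For day 15 against day 0 these shares were 5.97%, 65.7% and 95.5%, for day 22 against day 15 they were 1.49%, 58.2% and 100%, for SCGB3A2+ against day 22 they were 11.9%, 68.7% and 100%, and for SCGB3A2- against day 22 they were 17.9%, 74.6% and 97%. False calls numbered 9 of 144 calls for the day 36 sorts and 8 of 119, 7 of 113, 1 of 121 and 13 of 139 for the other comparisons in that order. Of 100 simulated lists with no change, camera put 3 under an unadjusted p of 0.05. The simulated probe sets varied independently, whereas the genes of a real list can vary together, with an estimated correlation of 0.769 for cell cycle genes. The simulation therefore does not show how often camera at the preset correlation passes such lists falsely.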

Results

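Gene expression was measured with arrays in RUES2, a human embryonic stem cell line, on its way to airway epithelium. The groups were undifferentiated cells at day 0 (n = 2), lung progenitors at day 15 sorted for high CD47 (n = 2), early airway cells at day 22 (n = 2), and cells sorted at day 36 as SCGB3A2- (n = 3) or SCGB3A2+ (n = 3). Arrays are named by their group and the labels' replicate letter, and their number, 12 in all, limits the precision. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Levels are RMA log2 values, and differences are log2 differences of group means ± limma's standard error (SE). Comparisons and gene lists were set before the data were examined. Arrays of the same group correlated at r = 0.979 for day 0, 0.991 for day 15, 0.987 for day 22, 0.991 to 0.993 for SCGB3A2- and 0.985 to 0.987 for SCGB3A2+. Correlations between day 0 and SCGB3A2+ included the lowest, at 0.854 to 0.872, and overlapped those between day 0 and day 22 (0.871 to 0.881). These are correlations across probe sets, which are not independent replicates.

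Of 23786 probe sets, 12205 (51.3%) differed among the 5 groups in limma's F-test, and 7839 of these spanned at least 2-fold between the highest and the lowest group mean. Day 0 had the highest mean for 4195 of the 12205, day 15 for 2559, day 22 for 1524, SCGB3A2- for 1454 and SCGB3A2+ for 2473. The pluripotency factor POU5F1 had its highest mean at day 0 (4.38) and lay between 1.46 and 1.80 in the other groups. Its day 0 level was low beside the median of the pluripotency list there (7.81). Its levels in the other groups were near the floor, so comparisons of POU5F1 among them say little. NKX2-1, the transcription factor that marks lung and thyroid fate, went from 2.97 at day 0 to 6.78 at day 15 and 6.88 at day 22, and was 7.63 in SCGB3A2+ and 4.13 in SCGB3A2- cells. SFTPB, the gene of a surfactant protein, stood at 3.23, 3.11 and 11.85 at days 0, 15 and 22, and at 12.25 in SCGB3A2+ and 9.96 in SCGB3A2- cells. AFP, a fetal liver and yolk sac protein, stood at 1.58, 4.05 and 11.40 over the same days and at 9.94 and 11.36 in the SCGB3A2+ and SCGB3A2- sorts.

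**Figure D1:**
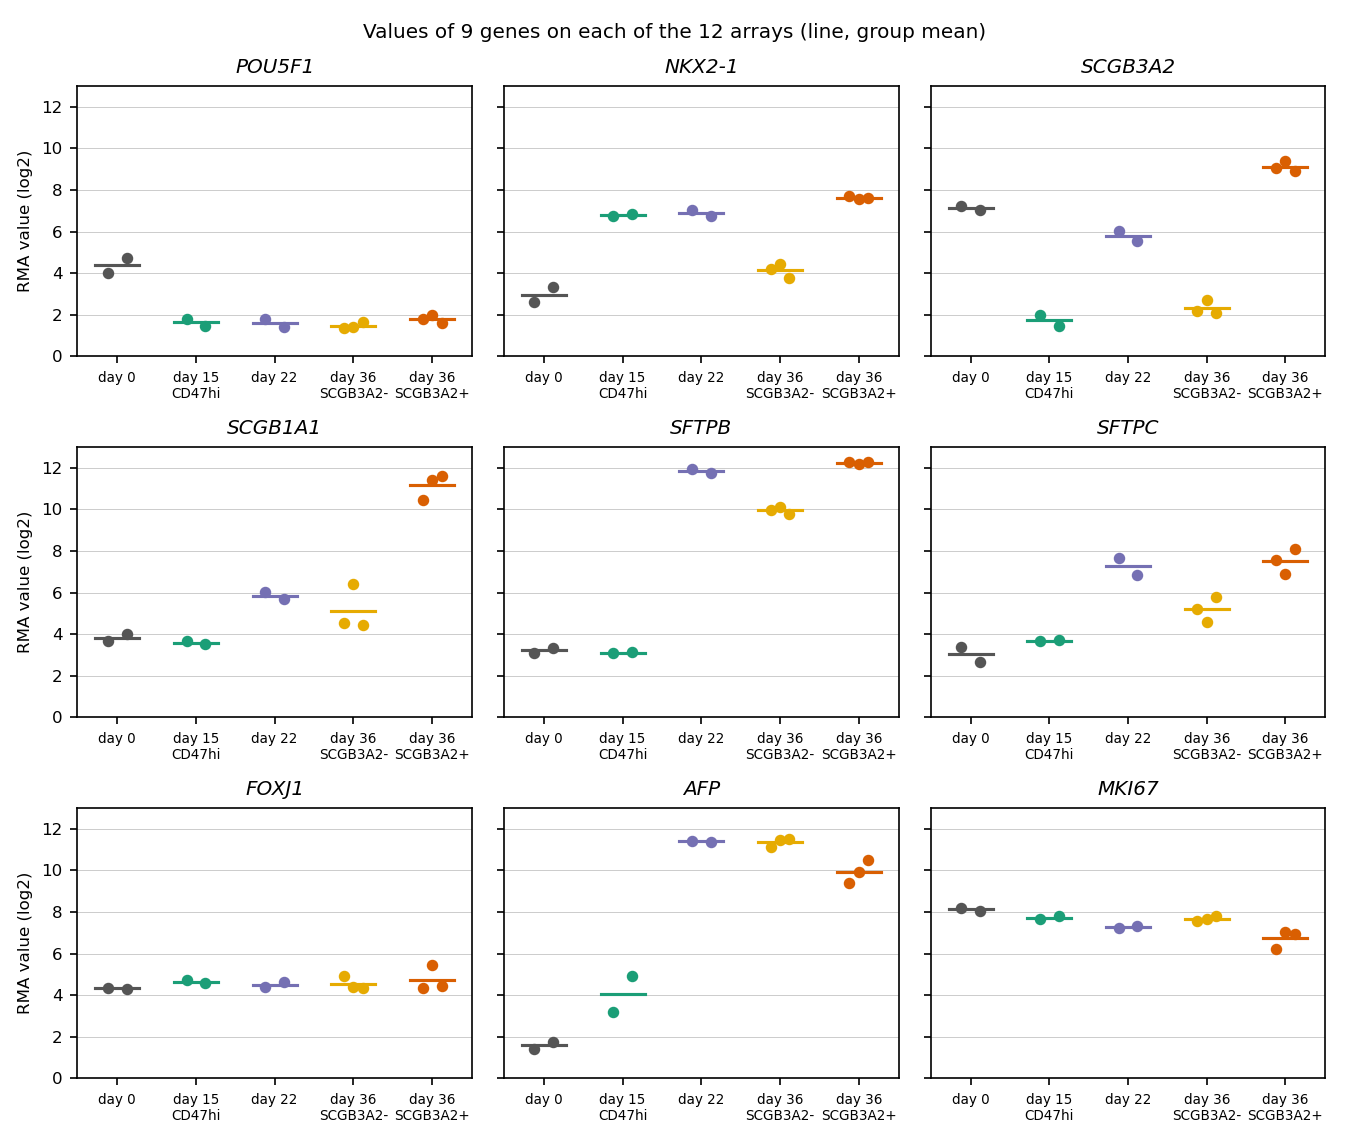
RMA log2 level (vertical axis) of 9 genes on each of the 12 arrays (points) by group, with lines at the group means. NKX2-1 was 7.63 in SCGB3A2+ and 4.13 in SCGB3A2- cells, and SFTPB rose from 3.11 at day 15 to 11.85 at day 22.

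The comparison of day 15 with day 0 asked how sorted lung progenitors differ from the undifferentiated cells. The sample titles name no sort at day 0, so differentiation and sorting cannot be told apart in it. Among the largest decreases were those of ESRG, a noncoding RNA of pluripotent cells (-8.85 ± 0.21, from 9.99 to 1.14, adjusted p = 4.18e-10), the secreted Wnt inhibitor SFRP2 (-7.40 ± 0.16), the RNA-binding protein gene L1TD1 (-6.43 ± 0.49) and DPPA4 (-6.16 ± 0.22). Increases were found for the ligand gene SHH (6.67 ± 0.38), the endoderm transcription factor FOXA1 (5.98 ± 0.29) and CPM (6.98 ± 0.21), a surface peptidase used to mark lung progenitors. GASK1B (7.49 ± 0.22), SEMA3C (6.81 ± 0.43), TGFB2 (6.27 ± 0.26) and CRH (5.76 ± 0.20), the gene of corticotropin-releasing hormone, rose too. NKX2-1 rose by 3.81 ± 0.24 (adjusted p = 4.78e-07), FOXA2 by 3.43 ± 0.12 and AFP by 2.47 ± 0.46, and POU5F1 fell by 2.74 (SE 0.24). CD47, on which the day 15 cells were sorted, was 1.90 ± 0.18 higher. SCGB3A2 was higher at day 0 (7.24 and 7.05 on its arrays) than at day 15 (1.998 and 1.459), a fall of -5.42 ± 0.26. The surfactant gene SFTPC (0.66 ± 0.44, adjusted p = 0.301), SFTPB (-0.11 ± 0.15, 0.636), the club cell gene SCGB1A1 (-0.23 ± 0.55, 0.805), the ciliogenesis factor FOXJ1 (0.32 ± 0.32, 0.504) and the hindgut factor CDX2 (1.11 ± 0.56, 0.168) did not pass. Neither did the proliferation marker MKI67 (-0.41 ± 0.23, adjusted p = 0.219, and 0.0487 without SCGB3A2+ A).

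By list, 17 of 18 measured pluripotency genes fell, 17 also when adjusted over the list alone, with PRDM14 at -5.75 ± 0.20 and VRTN at -4.75 ± 0.21 (camera adjusted p = 1.23e-14). The early lung epithelium list had 18 of 19 genes higher and 1 lower, the same counts adjusted over the list alone, with SFTA3 at 5.04 ± 0.18 (camera adjusted p = 8.13e-13). Definitive and foregut endoderm genes rose for 7 of 14 and none fell (7 and 0 adjusted over the list alone, camera adjusted p = 2.35e-04), with GATA6 at 4.43 ± 0.18 and SOX17 at 1.75 ± 0.19. Immediate early and stress genes, such as JUN (3.72 ± 0.19) and DUSP1 (2.93 ± 0.20), rose for 13 of 18 and fell for 2 (13 and 3 adjusted over the list alone, camera adjusted p = 2.47e-05). These 4 were the lists of this comparison whose calls also held with an estimated correlation (adjusted p = 0.0159, 0.013, 0.0247 and 0.0247 in that order). For the immediate early and stress genes, a part of the sort itself in the rise was not tested.

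Epithelial genes rose for 13 of 19 and 6 did not pass (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.72e-07 and adjusted p = 0.109 with an estimated correlation). The tight junction gene CLDN4 differed by 3.74 ± 0.17 and the keratin KRT19 by 3.72 ± 0.32. Canonical Wnt targets rose for 10 of 14 (11 adjusted over the list alone), including LEF1 (5.67 ± 0.24), RNF43 (3.17 ± 0.21) and the R-spondin receptor LGR5 (3.94 ± 0.38), at camera adjusted p = 3.36e-07 and adjusted p = 0.0508 with an estimated correlation. BMP targets rose for 6 of 9 (6 adjusted over the list alone, camera adjusted p = 0.00245 and adjusted p = 0.316 with an estimated correlation). ID1 differed by 1.61 ± 0.22. FGF targets fell for 8 of 14 and rose for 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00105 and adjusted p = 0.0944 with an estimated correlation). ETV4 differed by -4.16 ± 0.28, SPRY4 by -5.86 ± 0.25 and DUSP6 by -3.23 ± 0.18. EGR1, an immediate early gene, went in the other direction by 3.57 ± 0.22. Among liver genes 11 of 19 rose and 8 did not pass (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00144 and adjusted p = 0.439 with an estimated correlation). TTR, the gene of a thyroid hormone carrier, differed by 4.88 ± 0.34 and the fibrinogen gene FGB by 4.20 ± 0.51.

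In all, 3853 probe sets were higher and 3646 lower at day 15 (31.5% of those tested), 1857 and 1691 of them by 2-fold or more. Of 25 cell cycle genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), with AURKB at -1.15 ± 0.21. Their camera adjusted p of 0.0205 was 0.766 with an estimated correlation, 0.323 without day 0 A and 0.0738 without day 15 B. Antigen presentation genes fell for 7 of 16 and rose for 1 (7 and 2 adjusted over the list alone), with HLA-DRA at -1.81 ± 0.14 and TAP1 at -1.70 ± 0.19. That list's camera adjusted p of 0.0377 was 0.159 without day 0 A, and its adjusted p = 0.316 with an estimated correlation.

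The comparison of day 22 with day 15 asked how the early airway stage differed from sorted progenitors. The sample titles name a sort for high CD47 at day 15 and none at day 22. Time and sorting therefore cannot be told apart in this comparison. The largest increase among the named genes was that of SFTPB (8.74 ± 0.15, adjusted p = 4.88e-11). Albumin, ALB, rose by 8.27 ± 0.28, AFP by 7.35 ± 0.46, ITIH2 by 7.21 ± 0.19 and the fibrinogen gene FGA by 6.88 ± 0.44. The mucin MUC13 (7.38 ± 0.36), GP2 (6.80 ± 0.39) and AGR2 (6.74 ± 0.42), which helps fold mucins, rose as well. Among the largest decreases were CRH (-5.68 ± 0.20), LEF1 (-4.74 ± 0.24), FAT3 (-4.65 ± 0.30), ANK2 (-4.44 ± 0.19) and LGR5 (-4.28 ± 0.38). SCGB3A2 rose by 4.06 ± 0.26 (adjusted p = 1.41e-06) and SFTPC by 3.57 ± 0.44, while FOXA2 fell by 0.87 (SE 0.12). At day 22 SCGB3A2 (6.01 and 5.57 on the arrays) was still below its day 0 level (7.24 and 7.05). SCGB1A1 rose by 2.25 ± 0.55 (adjusted p = 0.0136), but not without day 15 B (0.057), day 15 C (0.0792) or day 22 A (0.0788). NKX2-1 (0.10 ± 0.24, adjusted p = 0.849), CD47 (-0.43 ± 0.18, 0.137), POU5F1 (-0.05 ± 0.24, 0.934), FOXJ1 (-0.14 ± 0.32, 0.846), CDX2 (0.74 ± 0.56, 0.44) and MKI67 (-0.43 ± 0.23, 0.25) did not pass.

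Alveolar type 2 genes rose for 15 of 17 (15 adjusted over the list alone, camera adjusted p = 2.62e-17). The lysosomal gene LAMP3 differed by 4.65 ± 0.30 and the phosphate transporter SLC34A2 by 5.31 ± 0.40. Secretory airway genes rose for 14 of 26 and 12 did not pass (15 higher adjusted over the list alone), among them AGR3 (4.60 ± 0.30) and CREB3L1 (2.45 ± 0.21), at camera adjusted p = 2.28e-10. The liver list had 16 of 19 genes higher (17 adjusted over the list alone), with SERPINA1 at 6.04 ± 0.25, at camera adjusted p = 5e-20. FGF targets rose for 11 of 14 and fell for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 4.05e-11). The feedback inhibitor gene DUSP6 differed by 4.16 ± 0.18 and SPRY2, another, by 2.40 ± 0.15. Ion and water transport genes rose for 6 of 16 (7 adjusted over the list alone), including the sodium channel subunit SCNN1A (3.57 ± 0.20) and the water channel AQP4 (4.63 ± 0.34), at camera adjusted p = 4.96e-04. These 5 lists also passed with an estimated correlation (adjusted p = 0.0465, 0.00411, 0.0465, 0.0106 and 0.0437 in that order).

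Intestine and stomach genes rose for 13 of 19 and fell for 1 (13 and 1 adjusted over the list alone, camera adjusted p = 7.73e-09 and adjusted p = 0.129 with an estimated correlation). The trefoil gene TFF1 differed by 6.20 ± 0.46 and the protease CTSE by 5.69 ± 0.39. Innate defence genes rose for 9 of 20 (9 adjusted over the list alone), among them the chemokines CCL20 (3.39 ± 0.24) and CXCL8 (3.80 ± 0.30), at camera adjusted p = 5.31e-06 and adjusted p = 0.119 with an estimated correlation. Xenobiotic and retinoid metabolism genes rose for 8 of 23 and fell for 1 (11 and 2 adjusted over the list alone, camera adjusted p = 6.48e-04 and adjusted p = 0.119 with an estimated correlation). NQO1 differed by 4.10 ± 0.24 and GSTA2 by 5.02 ± 0.54. Canonical Wnt targets fell for 9 of 14 and rose for 2 (10 and 2 adjusted over the list alone), and the inhibitor genes DKK1 (4.64 ± 0.35) and WIF1 (2.93 ± 0.24) were higher (camera adjusted p = 3.21e-04; adjusted p = 0.119 with an estimated correlation). Mesenchymal genes fell for 8 of 19 and rose for 1 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00594 and adjusted p = 0.0606 with an estimated correlation). The collagen COL1A1 differed by -2.59 ± 0.15 and LUM by 3.72 ± 0.42. Cell cycle genes fell for 6 of 25 (8 adjusted over the list alone, camera adjusted p = 0.00153 and adjusted p = 0.607 with an estimated correlation). BUB1B differed by -1.18 ± 0.24. With the replicate block, in groups where the letters were not shown to pair arrays, 1 of the 25 fell in place of 6, and the calls of CENPF (adjusted p = 0.0737), BUB1 (0.103) and MCM6 (0.138) were among those that ended.

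At day 22, 2129 probe sets were higher and 2514 lower than at day 15 (19.5% of those tested), 1129 and 920 of them by 2-fold or more. The counts were 1364 higher and 1495 lower without day 15 C, 1426 lower without day 15 B and 1536 lower without day 22 C.

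**Figure D2:**
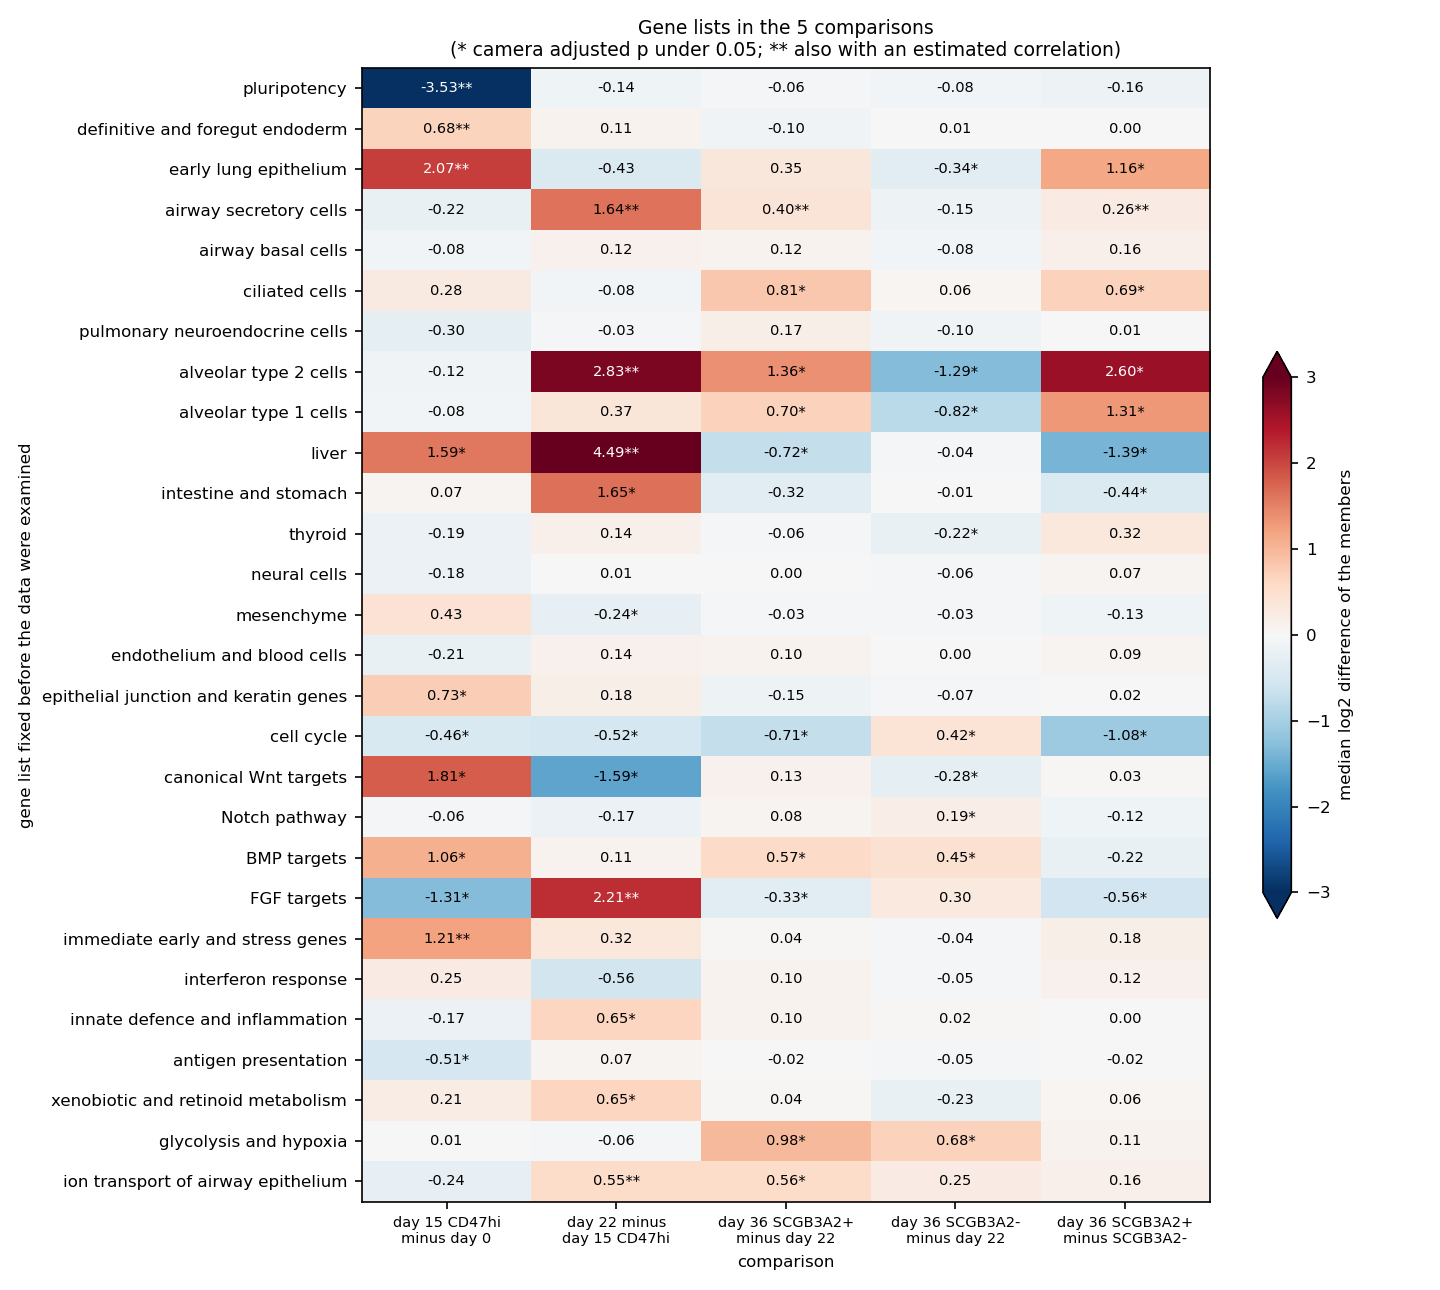
Median log2 difference (colour and number) of the 28 gene lists (vertical axis) in each of the 5 comparisons (horizontal axis), with * for a camera adjusted p under 0.05 and ** where it also held with an estimated correlation. The alveolar type 2 list had its highest median at day 22 against day 15 (2.83) among the comparisons between days, and was 2.60 in SCGB3A2+ against SCGB3A2-.

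SCGB3A2+ cells of day 36 were compared with day 22 to ask how the sorted airway population differed from that stage. The sample titles name no sort at day 22, so time and sorting cannot be told apart here. Among the largest increases were those of haptoglobin, HP (8.003 ± 0.48, adjusted p = 8.37e-06), CHI3L2 (5.35 ± 0.35), SCGB1A1 (5.30 ± 0.51, from 5.85 to 11.16), the chemokine CXCL17 (4.15 ± 0.21), the surfactant gene SFTPA1 (4.14 ± 0.40), the antiprotease SLPI (4.06 ± 0.34) and complement C3 (3.93 ± 0.27). Among the decreases were those of the protease MEP1A (-3.92 ± 0.46), the cadherin CDH17 (-3.49 ± 0.49), REG4 (-3.46 ± 0.40) and the retinol carrier RBP4 (-3.40 ± 0.48). ATP6V0D2, a proton pump subunit, fell by 5.12 (SE 0.52) and the Wnt inhibitor WIF1 by 3.31 (SE 0.22). SCGB3A2, on which the cells were sorted, was 3.32 ± 0.24 higher. SFTPC (0.25 ± 0.40, adjusted p = 0.759), POU5F1 (0.21 ± 0.22, 0.628), FOXJ1 (0.24 ± 0.29, 0.678) and MKI67 (-0.53 ± 0.21, 0.125) did not pass. SFTPB (0.41 ± 0.14, adjusted p = 0.0765) passed with an intensity trend and robust variances (0.0247) or with dim probe sets left out (0.0499). CDX2 (-1.47 ± 0.51, adjusted p = 0.081) passed with the replicate block (0.0441) or without day 22 A (0.0118).

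Further differences passed narrowly. NKX2-1 rose by 0.75 ± 0.22 (adjusted p = 0.0462), with 0.0989 under the replicate block. Its adjusted p was 0.0646 without day 15 B or day 15 C, 0.0861 without day 22 A, 0.29 without day 22 C, 0.0645 without SCGB3A2- A, and 0.116, 0.0744 and 0.0844 without SCGB3A2+ A, B and C. FOXA2 rose by 0.46 ± 0.11 (adjusted p = 0.0205), with 0.0822 from only the arrays compared, 0.0756 without day 22 A, 0.139 without day 22 C and 0.0559 without SCGB3A2+ B. CD47 rose by 0.72 ± 0.17 (adjusted p = 0.0152), with 0.181 without day 22 C and 0.0529 without SCGB3A2+ A. AFP fell by 1.46 (SE 0.41, adjusted p = 0.0364), with 0.135 without day 22 A, 0.17 without day 22 C, 0.0535 and 0.0516 without SCGB3A2- B and C, and 0.118 and 0.0733 without SCGB3A2+ A and B.

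Secretory airway genes rose for 11 of 26 and fell for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 2.88e-06). The mucin MUC1 differed by 2.81 ± 0.24. This was the list whose call also held with an estimated correlation (adjusted p = 0.0214). Ciliated cell genes rose for 7 of 23 (14 adjusted over the list alone, camera adjusted p = 1.45e-06 and adjusted p = 0.434 with an estimated correlation). The dynein DNAH5 differed by 1.85 ± 0.21. Alveolar type 2 genes rose for 10 of 17 and fell for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 1.45e-06 and adjusted p = 0.429 with an estimated correlation). The amino acid transporter SLC6A14 differed by 2.95 ± 0.33 and the protease NAPSA by 2.50 ± 0.29. Alveolar type 1 genes rose for 7 of 14 and fell for 1 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00116 and adjusted p = 0.234 with an estimated correlation). CLIC5 differed by 1.59 ± 0.20. The ion transport list rose for 7 of 16 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.64e-04 and adjusted p = 0.0688 with an estimated correlation). The sodium channel subunit genes SCNN1B and SCNN1G differed by 4.33 ± 0.24 and 2.48 ± 0.31. Glycolysis and hypoxia genes rose for 9 of 19 and fell for 1 (10 and 1 adjusted over the list alone, camera adjusted p = 1.54e-05 and adjusted p = 0.487 with an estimated correlation). The oxygen-sensing hydroxylase EGLN3 differed by 3.35 ± 0.49. BMP targets rose for 3 of 9 and fell for 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00756 and adjusted p = 0.487 with an estimated correlation). ID4 differed by 1.40 ± 0.20.

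Cell cycle genes fell for 11 of 25 (19 adjusted over the list alone) at camera adjusted p = 2.89e-07 and adjusted p = 0.487 with an estimated correlation, with AURKB at -1.02 ± 0.19 (adjusted p = 0.00542, and 0.079 without day 22 C). Liver genes fell for 8 of 19 and rose for 2 (9 and 2 adjusted over the list alone), with TTR at -2.86 ± 0.31 and VTN, a plasma adhesion protein, at -2.74 ± 0.34, and HP in the other direction. The liver list's camera adjusted p of 0.00265 was 0.0521 without day 22 C, and its adjusted p = 0.558 with an estimated correlation. Intestine and stomach genes fell for 8 of 19 and rose for 3 (9 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0538; adjusted p = 0.702 with an estimated correlation). Its camera adjusted p was 0.0432 after a repeated quantile normalization, 0.037 after centring, 0.00318 without day 22 A and 0.0184 without SCGB3A2+ C. FGF targets fell for 5 of 14 and rose for 1 (5 and 1 adjusted over the list alone), with the phosphatase DUSP5 at -2.22 ± 0.30. Their camera adjusted p of 0.0316 was 0.0574 from only the arrays compared, 0.0804 with dim probe sets left out, 0.05 without day 0 A or day 0 C and 0.0523 without SCGB3A2+ A, and the list had an adjusted p = 0.429 with an estimated correlation. In all, 1606 probe sets were higher and 1833 lower than at day 22 (14.5% of those tested), 487 and 576 of them by 2-fold or more. From only the arrays compared, 1869 probe sets differed in place of 3439, and 44.6% of the 1869 were higher. The counts were 1021 higher without day 22 A, 464 higher and 548 lower without day 22 C (303 and 359 of them by 2-fold or more), and 1023 higher and 1170 lower without SCGB3A2+ A.

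SCGB3A2- cells of day 36 were compared with day 22 in the same way and with the same limit. SFTA3 was lower at -3.66 ± 0.17 (adjusted p = 2.33e-06), NKX2-1 at -2.75 ± 0.22 (6.88 to 4.13, adjusted p = 3.37e-05) and SFTPB at -1.88 ± 0.14. The neuropeptide gene NMU (-4.56 ± 0.26), the matrix gene LUM (-3.997 ± 0.38) and the lipid receptor S1PR3 (-3.82 ± 0.22) fell too. DLK1, a fetal growth regulator (4.77 ± 0.60), the calcium-binding protein gene CALB1 (4.37 ± 0.42), C3 (3.998 ± 0.27), the copper carrier CP (3.65 ± 0.58), lysozyme, LYZ (3.54 ± 0.40), and HP (3.40 ± 0.48) rose. L1TD1, a gene of pluripotent cells, rose by 3.26 ± 0.45 (adjusted p = 0.00102). SCGB3A2, on which the cells were sorted, was lower at -3.47 ± 0.24. SFTPC fell by 2.07 (SE 0.40, adjusted p = 0.00813, and 0.0935 without day 22 A). CD47 fell by 0.73 (SE 0.17, adjusted p = 0.0215), with 0.0532 under the replicate block, 0.183 without day 22 A and 0.0695 and 0.0716 without SCGB3A2- A and B. AFP (-0.04 ± 0.41, adjusted p = 0.978), CDX2 (0.14 ± 0.51, 0.928), FOXA2 (-0.12 ± 0.11, 0.624), POU5F1 (-0.14 ± 0.22, 0.806), FOXJ1 (0.04 ± 0.29, 0.97) and MKI67 (0.40 ± 0.21, 0.33) did not pass. Nor did SCGB1A1 (-0.74 ± 0.51, adjusted p = 0.471), which had 0.0359 without SCGB3A2- B.

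None of the 9 lists that passed camera here held with an estimated correlation. Alveolar type 2 genes fell for 9 of 17 and rose for 1 (10 and 1 adjusted over the list alone, camera adjusted p = 2.46e-06 and adjusted p = 0.388 with an estimated correlation). LPCAT1, an enzyme of surfactant lipid, differed by -2.25 ± 0.17 and LAMP3 by -2.27 ± 0.27. Alveolar type 1 genes fell for 8 of 14 and rose for 2 (9 and 2 adjusted over the list alone, 7 and 1 with the replicate block, camera adjusted p = 2.46e-06 and adjusted p = 0.129 with an estimated correlation). PDPN differed by -2.44 ± 0.27 and EMP2 by -1.84 ± 0.17. The early lung list fell for 7 of 19 and rose for 2 (9 and 3 adjusted over the list alone, camera adjusted p = 6.9e-04 and adjusted p = 0.227 with an estimated correlation). CPM differed by -3.29 ± 0.19 and HOPX by -2.75 ± 0.18. Notch pathway genes rose for 2 of 18 (2 adjusted over the list alone), the target HEY1 (2.91 ± 0.27) and the feedback gene NRARP (0.99 ± 0.18), at camera adjusted p = 0.00742 and adjusted p = 0.246 with an estimated correlation. BMP targets rose for 4 of 9 and fell for 1 (4 and 1 adjusted over the list alone), with ID3 at 1.69 ± 0.21 and ID1 at 1.62 ± 0.20 and ATOH8 at -1.58 ± 0.26. Their camera adjusted p of 0.0148 was 0.0547 with dim probe sets left out, and the list had an adjusted p = 0.548 with an estimated correlation. Glycolysis and hypoxia genes rose for 4 of 19 and fell for 1 (10 and 1 adjusted over the list alone), with EGLN3 at 2.35 ± 0.49 (adjusted p = 0.0129, and 0.116 without day 22 C). With the replicate block 3 rose and 0 fell, and the calls of VEGFA (adjusted p = 0.0662) and HK2 (0.0693) ended. The list had a camera adjusted p = 1e-04 and an adjusted p = 0.548 with an estimated correlation.

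In the cell cycle list 1 of 25 genes rose, MCM3 (0.72 ± 0.19), and 0 passed adjusted over the list alone, with a median of 0.42 (camera adjusted p = 1.6e-04; adjusted p = 0.615 with an estimated correlation). MCM3 passed at 0.0384 and stood at 0.0748 with the replicate block, 0.0578 without day 15 B or C, 0.179 and 0.142 without day 22 A and C, 0.0817, 0.101 and 0.109 without SCGB3A2- A, B and C and 0.0503 without SCGB3A2+ C. Of 9 thyroid genes 1 fell, the deiodinase IYD (-1.13 ± 0.20, adjusted p = 0.00504, and 0.0664 without day 22 A), as it did adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.388 with an estimated correlation). Wnt targets fell for 3 of 14 (3 adjusted over the list alone), with WIF1 at -1.77 ± 0.22. Their camera adjusted p of 0.0362 was 0.196 without day 22 A and 0.0777 without SCGB3A2- C, and the list had an adjusted p = 0.548 with an estimated correlation. Xenobiotic and retinoid metabolism genes fell for 5 of 23 and rose for 1 (7 and 2 adjusted over the list alone, 6 and 2 with the replicate block), with CYP1B1 at -3.11 ± 0.22 and CYP1A1 at -3.08 ± 0.29. The list did not pass (camera adjusted p = 0.0551; adjusted p = 0.548 with an estimated correlation). It passed from only the arrays compared (0.0306), with dim probe sets left out (0.0334), with the block (0.0469) and, narrowly, after centring (0.05). Without single arrays it passed for day 15 B or C (0.0449), day 22 A (0.0199), SCGB3A2- A (0.0427) and SCGB3A2+ A, B or C (0.0412, 0.0418 and 0.0456), and its highest value was 0.228, without day 22 C. In all, 892 probe sets were higher and 986 lower than at day 22 (7.9% of those tested), 342 and 490 of them by 2-fold or more. The counts were 432 higher and 573 lower without day 22 A, 376 and 559 without day 22 C, 509 and 649 without SCGB3A2- B, and 500 and 642 without SCGB3A2- C.

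The comparison of both sorts at day 36 asked which genes go with SCGB3A2 in cells of the same age. SCGB1A1, the secretoglobin of club cells, was 6.04 ± 0.45 higher in SCGB3A2+ cells (11.16 against 5.12, adjusted p = 4.27e-06). Other genes higher there were the growth factor PTN (5.36 ± 0.35), the receptor kinase ROS1 (5.14 ± 0.27), the iron reductase CYBRD1 (5.11 ± 0.17), SFTPA1 (5.002 ± 0.36), SFTA3 (4.96 ± 0.15), AQP4 (4.76 ± 0.27), the kinase LRRK2 (4.70 ± 0.31) and ZNF385B (4.67 ± 0.20). NKX2-1 was 3.50 ± 0.20 higher (adjusted p = 7.3e-07), SFTPC 2.32 ± 0.36, SFTPB 2.29 ± 0.12, CD47 1.46 ± 0.15 and FOXA2 0.58 ± 0.10. SCGB3A2, the gene of the sort, was 6.79 ± 0.21 higher. Lower in SCGB3A2+ cells were the carbonic anhydrase CA4 (-3.65 ± 0.32), CALB1 (-3.50 ± 0.38), the steroid carrier SERPINA6 (-3.45 ± 0.27), the bile acid enzyme AKR1D1 (-3.41 ± 0.36), DLK1 (-3.30 ± 0.54), LIN28A, an RNA-binding protein of fetal and stem cells (-3.28 ± 0.38), and DUSP5 (-3.22 ± 0.27). MKI67 was lower at -0.93 ± 0.19 (adjusted p = 0.0041). AFP was lower at -1.42 ± 0.37 (adjusted p = 0.0161), but not without SCGB3A2- B (0.0537), SCGB3A2- C (0.0577) or SCGB3A2+ A (0.0709). CDX2 was lower at -1.60 ± 0.46 (adjusted p = 0.0254), but not without SCGB3A2- B (0.0722), SCGB3A2- C (0.0849), SCGB3A2+ B (0.0767) or SCGB3A2+ C (0.0578). POU5F1 (0.34 ± 0.20, adjusted p = 0.274) and FOXJ1 (0.20 ± 0.26, 0.674) did not pass.

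**Figure D3:**
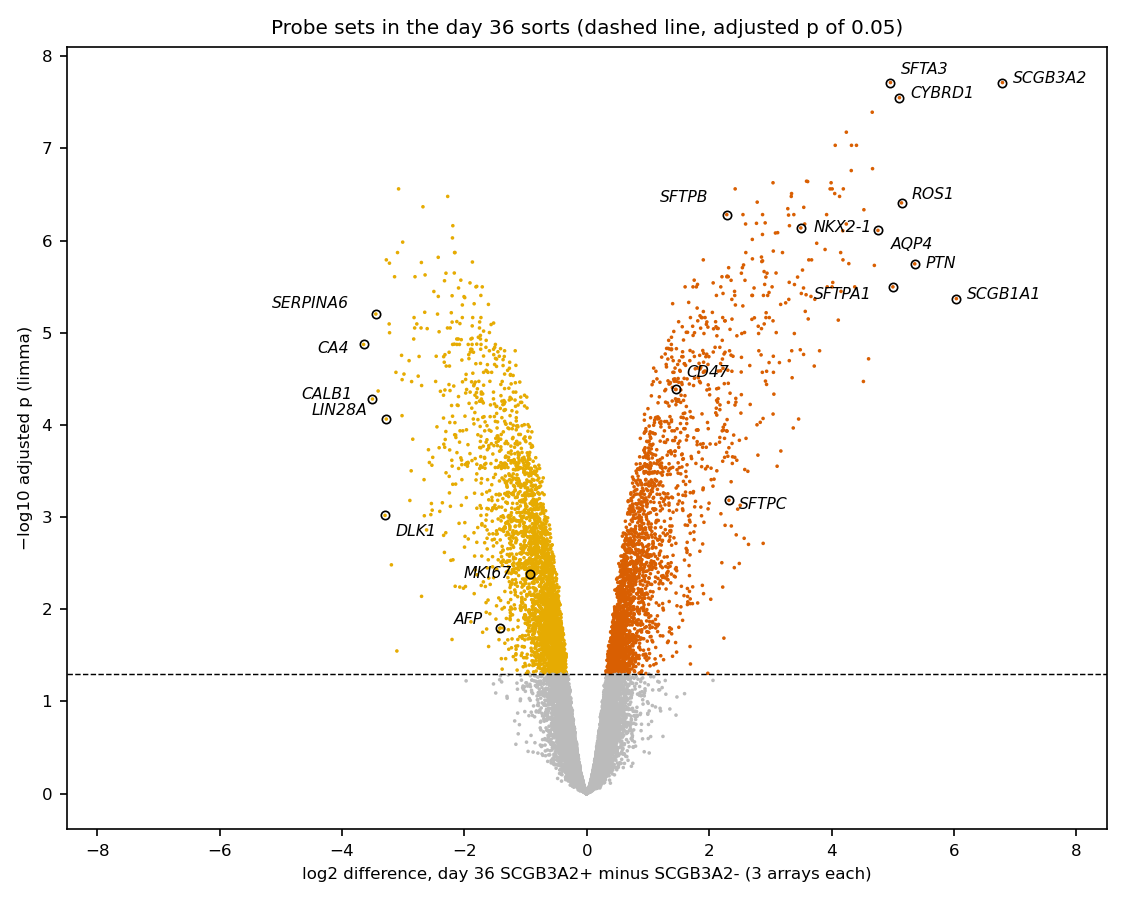
Log2 difference of SCGB3A2+ minus SCGB3A2- (horizontal axis) against -log10 of limma's adjusted p (vertical axis) for each probe set, with a dashed line at an adjusted p of 0.05. SCGB1A1 lay at 6.04 and CA4 at -3.65.

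Alveolar type 2 genes were higher in SCGB3A2+ cells for 13 of 17 and lower for 2 (13 and 2 adjusted over the list alone, camera adjusted p = 8.67e-11 and adjusted p = 0.13 with an estimated correlation). LAMP3 differed by 4.18 ± 0.24 and NAPSA by 4.15 ± 0.26. Alveolar type 1 genes were higher for 10 of 14 and lower for 2 (10 and 2 adjusted over the list alone, camera adjusted p = 1.84e-06 and adjusted p = 0.0661 with an estimated correlation). PDPN differed by 3.89 ± 0.24 and EMP2 by 2.77 ± 0.15. Secretory airway genes were higher for 11 of 26 (11 adjusted over the list alone), among them CYP4B1 (4.19 ± 0.27), SLPI (4.15 ± 0.30) and MUC1 (3.03 ± 0.22), at camera adjusted p = 1.55e-05. The secretory call was the one that held with an estimated correlation (adjusted p = 0.0317). The early lung list was higher for 11 of 19 and lower for 4 (11 and 5 adjusted over the list alone, camera adjusted p = 9.57e-04 and adjusted p = 0.13 with an estimated correlation). HOPX differed by 3.61 ± 0.17 and CPM by 2.54 ± 0.17. Ciliated cell genes were higher for 11 of 23 (11 adjusted over the list alone, camera adjusted p = 0.00109 and adjusted p = 0.51 with an estimated correlation). DNAH5 differed by 1.94 ± 0.19, SNTN by 1.81 ± 0.42 and CIMAP3 by 1.27 ± 0.21. The list's median difference was 0.69, against 0.06 over 5291 probe sets of like level (2.29 to 3.76). The median level of the list's members was 3.29 in SCGB3A2+ and 2.71 in SCGB3A2- cells, below the array medians and toward the floor.

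Cell cycle genes were lower in SCGB3A2+ cells for 23 of 25 (23 adjusted over the list alone, camera adjusted p = 2.02e-12 and adjusted p = 0.369 with an estimated correlation). The replication genes MCM3 and MCM5 differed by -1.40 ± 0.17 and -1.41 ± 0.19, and the mitotic kinase AURKB by -1.41 ± 0.17. Liver genes were lower for 9 of 19 and higher for 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.00115 and adjusted p = 0.496 with an estimated correlation). VTN differed by -3.12 ± 0.30 and AMBP by -2.75 ± 0.27. HP, by 4.60 ± 0.43, and the fibrinogen gene FGG, by 2.37 ± 0.23, went in the other direction. Intestine and stomach genes were lower for 6 of 19 (6 adjusted over the list alone), with the brush border gene VIL1 at -2.03 ± 0.20 and the pancreas and duodenum factor PDX1 at -1.71 ± 0.23. That list's camera adjusted p of 0.0103 was 0.133 without SCGB3A2+ B, and its adjusted p = 0.557 with an estimated correlation. FGF targets were lower for 7 of 14 and higher for 1 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00109 and adjusted p = 0.13 with an estimated correlation). ETV4 differed by -2.46 ± 0.23 and ETV5 by -1.45 ± 0.18, and DUSP4 by 1.53 ± 0.17. In all, 2400 probe sets were higher and 3040 lower in SCGB3A2+ than in SCGB3A2- cells (22.9% of those tested), 859 and 916 of them by 2-fold or more.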

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

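The tests of carry-over between the day 36 sorts were chosen only after the levels they use had been seen. Both sorts were set against the same day 22 arrays, and the results given here are those where the sorts went in opposite directions. The sample titles name no sort at day 22, so time and sorting cannot be told apart in differences from day 22. By sorting alone, genes that go with SCGB3A2 would lie on either side of an unsorted day 22. Opposite directions therefore need not mean a change with time. SCGB3A2+ cells were higher and SCGB3A2- cells lower than day 22 at 153 probe sets, and the reverse held at 92. Independent lists with the same numbers of calls would share 66.6 and 68.7, and the highest count in 20 simulated sets of unchanged groups, with the day 22 arrays shared in the same way, was 0 for both. The first number leaves out the shared arrays, whose noise moves both differences the same way, and the second leaves out real effects. Day 22 has too few arrays to be split. The counts were 62 and 17 without day 22 A, 46 and 19 without day 22 C, and 98 and 46 without SCGB3A2- C, and the second was 40 without SCGB3A2- B.

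Lists that moved apart between the sorts, by the direct comparison of SCGB3A2+ minus SCGB3A2-, were alveolar type 2 genes (median 2.60), alveolar type 1 genes (1.31) and cell cycle genes (-1.08). These passed camera with opposite signs against day 22. With an estimated correlation none of these calls held, at adjusted p = 0.13, 0.0661 and 0.369 between the sorts, 0.429, 0.234 and 0.487 for SCGB3A2+ against day 22, and 0.388, 0.129 and 0.615 for SCGB3A2- against day 22.

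Among named genes that rose in one sort and fell in the other against day 22, the direct log2 difference was 6.79 for SCGB3A2, the gene of the sort, 5.14 for ROS1, 5.11 for CYBRD1, 4.96 for SFTA3, 4.76 for AQP4 and 4.67 for ZNF385B. For these 6 genes every call held whichever of the 12 arrays was left out. PTN (5.36) lost its fall in SCGB3A2- cells without day 22 A (adjusted p = 0.0769), day 22 C (0.136), SCGB3A2- A (0.066) or SCGB3A2- C (0.0706). LRRK2 (4.70) lost that call without day 22 A (0.101). CA4 (-3.65) lost its rise in SCGB3A2- cells without day 22 A (0.0991) or SCGB3A2- C (0.0517), and SERPINA6 (-3.45) its fall in SCGB3A2+ cells without day 22 C (0.159). NKX2-1 (3.50) kept its fall in SCGB3A2- cells without any 1 array, and its rise in SCGB3A2+ cells ended with the replicate block (0.0989), and without day 15 B or C (0.0646), day 22 A (0.0861), day 22 C (0.29), SCGB3A2- A (0.0645), or SCGB3A2+ A, B or C (0.116, 0.0744 and 0.0844). CD47 (1.46) lost its rise in SCGB3A2+ cells without day 22 C (0.181) or SCGB3A2+ A (0.0529), and its fall in SCGB3A2- cells with the replicate block (0.0532), and without day 22 A (0.183), SCGB3A2- A (0.0695) or SCGB3A2- B (0.0716). The direct difference between the sorts passed for all 12 genes in the main fit, as the choice of these genes required. It spans both opposite changes. Its passing with arrays left out or with the replicate block therefore follows largely from that choice and is no further support.

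Of the 10 splits of the 6 day 36 arrays into 3 and 3, 1 gave as many probe sets as the real one, the real one itself, with 5440. The highest of the others was 0, also among the 4 splits that part every pair of letters. With 10 splits the share cannot fall under 0.1, so they are too few to test chance.

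Cells carried over between the sorts were weighed as the source of liver transcripts in SCGB3A2+ cells, such as ALB at 10.98, and of alveolar type 2 transcripts in SCGB3A2- cells, where levels ran from 2.34 for LRRK2 to 9.96 for SFTPB and no call of presence was made. Carried-over cells bring all their transcripts in one proportion, which cannot exceed the ratio of the genes that differ most between the sorts. The 20 genes lowest in SCGB3A2+ cells stood there at up to 12.4% of their SCGB3A2- level, whereas the median of the 16 liver genes with a level above 6 in SCGB3A2- cells was 37.1% (lower quartile 20%), with VTN (11.5%) itself one of the 20 genes that set the limit. The 20 genes lowest in SCGB3A2- cells stood at up to 5.29%, whereas the median of the 14 alveolar type 2 genes with a level above 6 in SCGB3A2+ cells was 15.1% (lower quartile 6.19%), with SFTPA1 (3.12%) and LRRK2 (3.85%) themselves among the 20 and SFTPB at 20.5%. Every gene outside the 20 lies above the limit by the way it was set, so the list medians could hardly fall below it. The comparison with the limit is therefore not an independent test. The values show only that whole sorted populations carried over at such a proportion would fall short of the median level of either list. Carry-over of a single kind of cell and expression in the sorted cells themselves, the biological alternative, stay open and may both contribute.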

How the results depend on the processing

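No named gene or list changed direction past the threshold under any alternative. Fitting only the arrays of the compared groups gave 834 higher and 1035 lower probe sets for SCGB3A2+ against day 22, in place of 1606 and 1833, whereas it gave 1039 and 1079 for SCGB3A2- against day 22 and 2455 and 3184 between the sorts, each above the counts from all arrays, and the cause was not tested. Leaving out each array in turn gave 1364 to 2398 higher and 1426 to 2877 lower at day 22 against day 15, 464 to 1915 higher and 548 to 2204 lower for SCGB3A2+ against day 22, and 376 to 1096 higher and 559 to 1169 lower for SCGB3A2- against day 22. The highest of these counts came without day 0 A or day 0 C. These gave the same numbers because either leaves 1 array at day 0, which adds nothing to the estimate of the spread. The day 0 arrays had the lowest correlation within a group (0.979) and the lowest array weights (0.455). In the comparisons just given, day 0 enters only through the estimate of the spread. The higher counts therefore came from leaving the day 0 spread out of that estimate. In the other comparisons, and in the F-test (11184 to 13058), the counts stayed within 1.5 times. All other settings, applied to these counts, also stayed within 1.5 times. With the replicate block, 5254 probe sets differed between the day 36 sorts in place of 5440, and 5391 in a paired fit of the day 36 arrays alone. Over 581 values of named genes (554 past the threshold), 24 calls were lost and 1 gained with the block. Among the differences given in the text, the block changed the calls of NKX2-1, CDX2, CD47, MCM3, VEGFA and HK2 against day 22, those of CENPF, BUB1 and MCM6 at day 22 against day 15, and no other. It moved a count of list members by more than 1.5 times in 9, 5, 5, 9 and 2 of 28 lists, in the order of the comparisons, by 1 or 2 genes each except for the cell cycle genes lower at day 22 than at day 15, 1 in place of 6. Calls lost were 29 with only the arrays compared, 11 after a repeated quantile normalization, 6 with array weights, 5 with an intensity trend and 3 after centring. Leaving out arrays ended 362 of 6648 calls and added 3. Over 140 list tests (50 past the threshold), the block ended 0 calls and added 2, the Notch pathway between the sorts (0.0309) and xenobiotic metabolism for SCGB3A2- against day 22 (0.0469 in place of 0.0551). An estimated correlation ended 39 list calls, and fry, which asks whether a list's genes move one way without comparing them with other genes, ended 8 and added 22. Further lists below the threshold passed without some arrays, with lowest values of 0.00197 for glycolysis and 0.0391 for thyroid genes between the sorts, 0.0104 for innate defence in SCGB3A2- and 0.0224 for early lung genes in SCGB3A2+ against day 22, and 0.0192, 0.0137, 0.0411 and 0.0463 for alveolar type 1, interferon, immediate early and thyroid genes at day 22 against day 15. Early lung genes in SCGB3A2+ against day 22 also passed from only the arrays compared (camera adjusted p = 0.0351). Alveolar type 1 genes at day 22 against day 15 also passed after centring (camera adjusted p = 0.0494). None of these further lists passed with an estimated correlation. The RMA values carry no measure of signal over background, so differences near the floor are limited by it in a way not measured here.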

Other observations

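The tests of RNA from late airway cells at day 0 and of undifferentiated cells in the SCGB3A2- sort, and the allowance for error in the test of HERVH transcripts, were chosen only after the results were seen. Between the day 36 sorts, Notch pathway genes were lower in SCGB3A2+ cells for 4 of 18 (4 adjusted over the list alone), among them the ligand JAG1 (-2.10 ± 0.15), HEY1 (-1.72 ± 0.24) and NRARP (-1.39 ± 0.16). The list did not pass (camera adjusted p = 0.0515; adjusted p = 0.348 with an estimated correlation). Its camera adjusted p was 0.0309 with the replicate block (0.0368 from the day 36 arrays alone), 0.0432 after a repeated quantile normalization and 0.0474 after centring. It was 0.0314 and 0.0375 without SCGB3A2- A and B, 0.0432 and 0.0266 without SCGB3A2+ B and C, and up to 0.144, without SCGB3A2+ A, in the rest. Innate defence genes went both ways, with 4 of 20 higher, such as lactoferrin, LTF (3.06 ± 0.32), and 7 lower, such as the defensin DEFB1 (-1.58 ± 0.16) and the chemokine CXCL5 (-1.65 ± 0.20) (4 and 7 adjusted over the list alone, camera adjusted p = 0.756). CYP1B1, an enzyme of xenobiotic and estrogen metabolism, was 3.98 ± 0.19 higher in SCGB3A2+ cells, on a list with 5 of 23 higher and 2 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.271). The sodium channel subunits SCNN1B (3.92 ± 0.21), SCNN1G (2.87 ± 0.28) and SCNN1A (1.96 ± 0.16) were higher in SCGB3A2+ cells, on an ion transport list with 4 of 16 higher and 3 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.194). LUM, a matrix gene, was 3.04 ± 0.34 higher in SCGB3A2+ cells on a mesenchyme list with 1 of 19 higher and 1 lower (1 and 0 adjusted over the list alone, 2 and 0 with the replicate block, camera adjusted p = 0.804).

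Lists of other cell types that passed camera in no comparison still held single genes that changed. At day 15 against day 0, neural genes rose for 2 of 15 and fell for 3 (the same adjusted over the list alone, camera adjusted p = 0.437), with the cytoskeletal gene MAP2 at 4.20 ± 0.22 and the neural progenitor gene NES at -1.90 ± 0.24. Genes of endothelium and blood fell for 3 of 16 (3 adjusted over the list alone, camera adjusted p = 0.118), with the receptors KDR at -6.42 ± 0.38 and TEK at -5.02 ± 0.16. Neuroendocrine genes fell for 5 of 13 and rose for 2 (5 and 2 adjusted over the list alone, camera adjusted p = 0.382), with the granin SCG3 at -4.83 ± 0.35. Airway basal cell genes rose for 3 of 14 and fell for 1 (3 and 1 adjusted over the list alone, camera adjusted p = 0.736), and between the sorts 2 were higher and 2 lower, with LAMB3 at 2.42 ± 0.27 and DST at -1.28 ± 0.17. Interferon response genes rose for 5 of 17 and fell for 1 (5 and 1 adjusted over the list alone), with IFI6 at 2.96 ± 0.29. The interferon list had a camera adjusted p = 0.116 (adjusted p = 0.316 with an estimated correlation), with 0.0474 when dim probe sets were left out and 0.0367 without day 15 C. No list past the threshold had a median, mean and test of different sign. Pluripotency genes in SCGB3A2- against day 22 were among the lists below it that did, with a median of -0.08 and a mean of 0.22.

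SCGB3A2 stood at 7.24 and 7.05 on the day 0 arrays, below SCGB3A2+ cells (8.89 to 9.39). Its day 0 levels were above day 15 (1.998 and 1.459), day 22 (6.01 and 5.57) and SCGB3A2- cells (2.06 to 2.7). RNA of late airway cells in the day 0 samples would need a share of 25.7%, and the 20 other genes that rose most from day 15 to SCGB3A2+ then needed far higher day 0 levels than measured, by a median of -5.07 (quartiles -6.01 to -4.48). SFTPB, for example, stood at 3.23 where 10.29 was needed, so this source is argued against. A transcript driven by a HERVH repeat in undifferentiated cells, as known for ESRG, was tested on 3 other transcripts known for it, and 1 of the 3, LINC-ROR (-1.16 ± 0.187), was lower at day 15 by 2-fold or more, while ABHD12B (-0.98 ± 0.151) and HHLA1 (-0.99 ± 0.158) lay within their error of 2-fold and all 3 were low at day 0 (2.58 to 3.74). The rule set beforehand counted 1 of 3 against the explanation, and the allowance for error, added later, made the outcome undecided. Other transcripts cannot show what drives SCGB3A2, so no conclusion is drawn from this test. The HERVH explanation stays open, as do cross-hybridisation, which probe-level values not used here could address, and expression of SCGB3A2 itself in stem cells.

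L1TD1 (3.26 ± 0.45), SALL4 (1.11 ± 0.26) and USP44 (1.27 ± 0.25), genes of pluripotent cells, were higher in SCGB3A2- cells than at day 22. SALL4 lost that call without day 22 A (adjusted p = 0.158), day 22 C (0.0661), SCGB3A2- B (0.0692) or SCGB3A2- C (0.0723), and USP44 without day 22 A (0.102). Undifferentiated cells left in the culture would need a share of 10.9%, and the 10 other members of the list with a day 0 level above 6 then lay below the level needed by a median of -1.88 (quartiles -2.58 to -0.306), with ESRG at 1.31 where 6.80 was needed, DPPA4 at 1.83 where 5.38 was needed, and LIN28A, LIN28B and TERF1 above it. These 10 are members that did not pass as higher, so some shortfall of their median is built in. The needed level also leaves out transcripts present at day 22, such as SALL4 at 5.92. Levels as far below the need as those of ESRG and DPPA4 still argue against such cells, at that share, as the only source. A fetal programme that shares L1TD1 and SALL4 with stem cells may account for the rise and was not tested.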
